A study of Homo sapiens with 53 samples.

How the data were processed

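Chromatin immunoprecipitation followed by paired-end sequencing (ChIP-seq) was carried out in HEK293T cells, a human embryonic kidney line, per the labels. Cells received DMSO, the solvent, or the compound BPK-25 at 30 µM for 72 h. The parental cells were immunoprecipitated with antibodies against CTCF or MBD3, and derived lines carrying Flag-tagged TET1, TET2 or TET3 with an antibody against Flag. The labels describe 53 samples in 18 groups, of which 29 were immunoprecipitates and 24 were sonicated input. Each immunoprecipitate group has 3 labelled replicates, except TET2 under DMSO with 2; the list of that group is named for 3 and was used as deposited.

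The analysis started from 10 deposited peak lists, 1 per target and treatment. The labels name 1 list for all replicates of a group. From this and the list names, the lists were taken as called on pooled replicates against input. FastQC 0.11.7, Bowtie2 2.3.4, SAMtools 1.9, MACS2 2.1.2, bedtools 2.25.0 and the genome build hg19 are named in the submitters' processing notes; their roles and parameters are not given in the sources used here. For each summit the deposited lists give a fold enrichment, which is a ratio of pileup to local background, and the -log10 of a p-value and of a q-value, all as computed by the authors' peak caller. The offset of each summit from the start of its interval is also given in the deposited lists. The lowest -log10 q lay between 1.30 and 1.31 in the 10 lists, at or just above the value of a q of 0.05. All coordinates are hg19 and 1-based.

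Intervals that overlapped or touched were merged into peaks, and each peak kept the position and values of its summit with the highest -log10 q. Fold enrichment and -log10 q served to describe, rank and filter peaks within a list. Because the lists hold MACS2 columns, the pileup (n fragments) and local background at each summit were solved from fold enrichment, taken as (n + 1) divided by (background + 1), and the Poisson -log10 p. Among summits with a pileup under 200, 100% came out within 0.02 of a whole number in each of the 10 lists. The lowest local background in a list was taken as its genome background, which follows the depth of the pooled libraries. It was 3.68 fragments for CTCF under DMSO and 2.58 under BPK-25, 3.21 and 2.57 for MBD3, 1.85 and 1.75 for TET1, 1.25 and 1.05 for TET2, and 1.70 and 1.65 for TET3. At the genome background the lowest pileup called lay between 8 and 11 fragments. Total read numbers per library were not used here.

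Lists were compared by overlap of at least 1 bp. A DMSO peak was called retained where it overlapped a BPK-25 peak of the same target, and a BPK-25 peak new where it overlapped no DMSO peak. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only and say nothing of the spread between replicates. The share given by position alone came from 200 circular shifts of the other list along each chromosome, with 1 random offset per chromosome. Lists were divided into deciles by -log10 q. Retention of CTCF peaks that overlapped another target was set against 10000 random sets of CTCF peaks of the same size, matched on decile of fold enrichment. Values of 2 lists at shared sites were taken where summits lay within 100 bp. With 1 pooled list per target and treatment, no test between treatments was possible, and differences between treatments have no replicate check.

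Regions were named by a rule fixed before the data were examined. Retention, overlap between targets within a treatment, and retention by strength and by co-occupancy were fixed then too. Values at shared sites, shares of the top-ranked CTCF peaks and overlaps of different targets across treatments were not. Neither were overlaps and MBD3 classes by CTCF decile, nor the classes of TET peaks at CTCF sites. For CTCF and MBD3 it took the 10 DMSO peaks of highest -log10 q on chromosomes 1 to 22 and X that were retained, the 10 highest with no BPK-25 peak within 1000 bp, and the 10 highest BPK-25 peaks with no DMSO peak within 1000 bp. For each TET protein it took 5 per class. Regions of high local background, 20 or more times the genome background, were singled out after their values were seen. Peaks of high local background were joined into regions where they lay within 100 kb of each other.

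Alternatives were a -log10 q of at least 5 or 10, chromosomes 1 to 22 and X only, intervals within 500 bp merged, 50% of the peak covered, summits within 200 bp, both lists limited to the same number of strongest peaks, a pileup requirement equal in both lists relative to background, shifts of 100 kb to 1 Mb, and matching on peak width. Alternatives chosen after seeing the data were a fold enrichment of at least 10, leaving out peaks of high local background, and leaving out the TET1 peaks that overlap TET3 peaks of the same treatment, from both lists or from the DMSO list alone. No hg19 sequence or annotation was used, so motifs, promoters and gene lists fixed beforehand were not analysed here, and regions are named by coordinates alone. A table of gene names on GRCh38.p14 was used only for the chromosome and length of genes and the number of protein-coding genes per chromosome.

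The recovery of pileups was tested on simulated data: 100% of 4655 simulated whole pileups were recovered within 0.02, and 0% of the pileups made fractional were taken for whole. Overlap counts on simulated lists equalled those of bedtools 2.31.1. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.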

Results

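The series concerns NuRD, a chromatin remodelling and deacetylase complex of which MBD3 is a subunit, at binding sites of CTCF, the zinc-finger protein that marks insulators and the anchors of chromatin loops. Its peak lists record where CTCF, MBD3 and Flag-tagged TET1, TET2 and TET3, the dioxygenases that oxidise 5-methylcytosine, were enriched in HEK293T cells after 72 h in DMSO or 30 µM BPK-25. There are 10 lists, each taken as called on the pooled replicates of 1 group, so the values below have no spread between replicates. The lists held 99587 CTCF, 82358 MBD3, 5951 TET1, 1233 TET2 and 14129 TET3 peaks under DMSO, and 245419, 243213, 447, 509 and 13360 peaks under BPK-25. The genome background, a measure of depth, was lower under BPK-25 for all 5 targets, at 70.0% of the DMSO value for CTCF, 79.9% for MBD3, 94.8% for TET1, 83.7% for TET2 and 97.0% for TET3. Fold enrichments are the authors' values at the summits.

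The first comparison asks how the CTCF sites of DMSO-treated cells fared under BPK-25. The BPK-25 list was longer, with 2.46 times as many peaks covering 86.5 Mb against 42.0 Mb, but its peaks were weak. The median fold enrichment was 11.3 (quartiles 5.26 and 38.3) under DMSO and 3.71 (3.04 and 4.73) under BPK-25. Peaks with a fold enrichment of 10 or more numbered 53019 under DMSO, or 53.2% of the list, and 2311 under BPK-25, or 0.942%. Of the DMSO peaks, 39.2% (95% interval 38.9 to 39.5) overlapped a BPK-25 peak, against 6.63% (range 6.04 to 7.26) after circular shifts and 10.7% after shifts of 100 kb to 1 Mb, and 83.3% of the BPK-25 peaks were new. The direction of the difference in number depended on the threshold: at a -log10 q of 10 or more the BPK-25 list had 47630 peaks and the DMSO list 80698, of which 16.8% were retained.

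Retention of CTCF peaks did not increase steadily with strength. It was 66.5% in the weakest decile of the DMSO list, where the median fold enrichment was 2.99, decreased to 24.4% in the 8th decile, where that median was 39.1, and was 70.6% in the strongest decile, where it was 120. Of the 1000 strongest DMSO CTCF peaks, 99.2% (98.4 to 99.7) overlapped a BPK-25 CTCF peak, and of the 10000 strongest 70.5% (69.6 to 71.4). The BPK-25 MBD3 list overlapped 99.5% (98.8 to 99.8) and 73.5% (72.6 to 74.4) of the same peaks, so such overlap was not particular to the CTCF immunoprecipitation. The sites kept at the top of the list were far less enriched, however. At 4992 shared sites of the strongest decile, the median pileup was 351 times the genome background under DMSO (quartiles 263 and 470) and 12.0 times under BPK-25 (8.54 and 16.3).

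**Figure D1:**
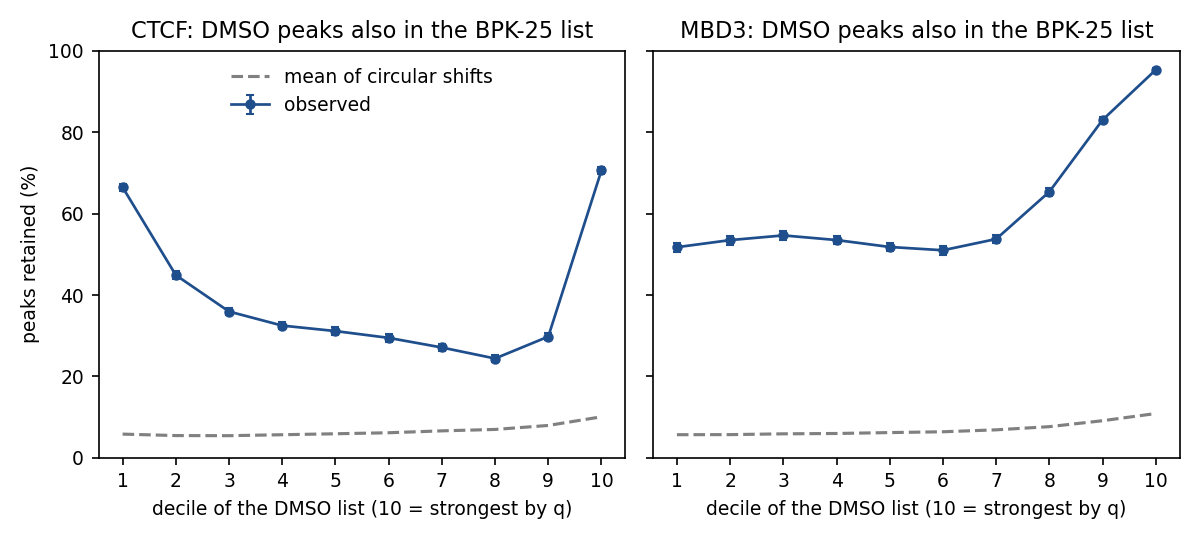
Share of DMSO peaks that overlap a BPK-25 peak of the same target, in percent, by decile of the DMSO list ranked on -log10 q, for CTCF (left) and MBD3 (right), with Clopper-Pearson 95% intervals as bars and the mean after circular shifts as a dashed line. CTCF retention is 66.5% in the weakest decile, 24.4% in the 8th and 70.6% in the strongest, whereas MBD3 retention is between 51.0% and 54.6% in the first 7 deciles and reaches 95.3% in the strongest.

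The most significant retained CTCF region was chromosome 17, 79074724 to 79076263, with a fold enrichment of 463 under DMSO and 12.1 under BPK-25. Chromosome 14, 21560049 to 21561421, had 428 and 13.5, and chromosome 1, 225662527 to 225663125, had 361 and 10.0. A set of 3 of the 10 retained regions lay close together on chromosome 4: 8626189 to 8627080, 8632016 to 8633016 and 8637779 to 8638480, with DMSO fold enrichments of 205, 154 and 170 and BPK-25 values of 5.31, 3.99 and 8.53. At these 3 the DMSO local background was 8.01, 10.6 and 9.76 times the genome background. It was 2.41 to 4.18 times at the other retained regions named by the rule. All 10 retained regions overlapped MBD3 peaks in both treatments. The strongest DMSO regions with no BPK-25 CTCF peak within 1000 bp were also highly enriched. Chromosome X, 100023613 to 100024269, had a fold enrichment of 230, chromosome 13, 77477663 to 77478124, of 220, and chromosome 12, 131400655 to 131401157, of 241. All 10 of these overlapped a DMSO MBD3 peak, 5 a BPK-25 MBD3 peak, and 10 a BPK-25 TET3 peak. Of the 10 top new CTCF regions, 8 lay where the local background was at least 20 times the genome background, such as chromosome 10, 42596926 to 42597148, at 3681 times, and each of the 10 overlapped a BPK-25 MBD3 peak.

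MBD3 peaks showed a different course. The BPK-25 list had 2.95 times as many peaks as the DMSO list, at about the same median fold enrichment, 3.77 (3.08 and 4.78) against 3.65 (2.96 and 5.26). Under DMSO, 5203 MBD3 peaks had a fold enrichment of 10 or more, and under BPK-25 2267. Of the DMSO peaks, 61.4% (61.0 to 61.7) were retained, against 7.07% after circular and 14.0% after local shifts (100 kb to 1 Mb). The BPK-25 CTCF list overlapped 60.3% (60.0 to 60.6) of the same peaks, so such overlap was not particular to the MBD3 immunoprecipitation. Of the BPK-25 MBD3 peaks, 78.2% were new. Retention was 51.7% in the weakest decile and 95.3% in the strongest. At 30930 shared sites the median pileup was 8.72 times the genome background under DMSO (5.60 and 14.9) and 10.5 times under BPK-25 (7.79 and 14.4).

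The strongest MBD3 regions were nevertheless less enriched under BPK-25. Chromosome 9, 100173977 to 100175142, had fold enrichments of 145 under DMSO and 9.81 under BPK-25, chromosome 1, 3163917 to 3164927, of 102 and 7.79, and chromosome 6, 36646213 to 36648610, of 70.0 and 6.59. An exception was chromosome X, 115004579 to 115005353, with 8.55 and 10.0, where the local background was 65.7 times the genome background. Of the 10 retained regions, 9 overlapped a DMSO CTCF peak. Among regions with no BPK-25 MBD3 peak within 1000 bp, chromosome 9, 91849266 to 91849942, had a DMSO fold enrichment of 38.7 and chromosome 3, 130064476 to 130064927, of 33.0. Of the top 10 new MBD3 regions, 7 lay in high local background, and chromosome 7, 63216140 to 63216534, with a fold enrichment of 19.4, and chromosome 5, 176018298 to 176019233, with 13.5, did not.

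The next comparison addresses the occupancy of CTCF sites by MBD3. Under DMSO, 36.9% of CTCF peaks (36.6 to 37.2) overlapped an MBD3 peak, against 2.48% after circular and 3.94% after local shifts, and 43.3% of MBD3 peaks overlapped a CTCF peak. The share was highest at both ends of the CTCF list, 55.4% in the weakest decile and 83.8% in the strongest, and 24.8% in the 8th, and at a -log10 q of 10 or more the share was 21.2%. Under BPK-25 the 2 lists were much alike: 69.0% of CTCF peaks (68.8 to 69.2) overlapped an MBD3 peak, against 6.67% after circular and 14.4% after local shifts, and 99.4% did so in the strongest decile. The BPK-25 MBD3 list overlapped 40.2% of the DMSO CTCF peaks, close to the 39.2% of the BPK-25 CTCF list. At shared sites the ratio of MBD3 to CTCF local background had quartiles of 0.958 and 1.01 under DMSO and 0.989 and 1.03 under BPK-25, against 0.775 and 1.25 for CTCF between treatments. The labels give 1 set of inputs per treatment for these cells, and part of the overlap may come from that shared control.

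CTCF peaks that carried MBD3 under DMSO were retained more often. Of 36778 such peaks, 76.8% (76.3 to 77.2) were retained, against 17.3% of the 62809 others and 46.6% (45.8 to 47.3) in random sets matched on fold enrichment. The same held for CTCF peaks that overlapped TET1, with 75.2% retained against 45.3% in matched sets, TET2, with 75.1% against 45.8%, and TET3, with 79.0% against 45.1%. These sets were not matched on MBD3. Under DMSO, 83.2% of TET1, 84.8% of TET2 and 82.6% of TET3 peaks overlapped an MBD3 peak. A relation of retention to TET apart from MBD3 was not tested. In each of the 10 deciles of strength, peaks with MBD3 were retained more often than peaks without it, from 55.6% against 13.1% in the 9th decile to 85.2% against 43.1% in the weakest. These shares describe the lists and are not a test between treatments. As 69.0% of BPK-25 CTCF peaks overlapped an MBD3 peak, they do not separate kept CTCF from signal that the CTCF and MBD3 lists have in common.

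**Figure D2:**
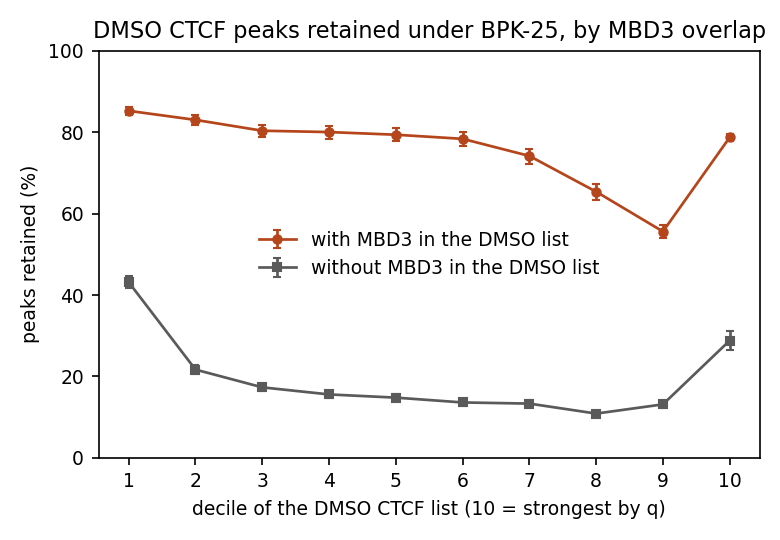
Share of DMSO CTCF peaks that overlap a BPK-25 CTCF peak, in percent, by decile of the DMSO CTCF list ranked on -log10 q, for peaks with (circles) and without (squares) an overlapping DMSO MBD3 peak, with Clopper-Pearson 95% intervals as bars. The circles lie above the squares in all 10 deciles, at 78.7% and 28.8% in the strongest.

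The TET lists differed in size and in how far their peak numbers differed between treatments. TET1 had 447 peaks under BPK-25 against 5951 under DMSO (ratio 0.0751), TET2 509 against 1233 (0.413) and TET3 13360 against 14129 (0.946). TET3 had more BPK-25 than DMSO peaks at a -log10 q of 5 or more, 6897 against 5404. At a -log10 q of 10 or more the ratio was 0.329 for TET1 and 0.916 for TET2. High local background held 21.3% of the BPK-25 TET1 peaks and 33.4% of the BPK-25 TET2 peaks, against 0.605% and 4.54% under DMSO. Without those peaks and without the -log10 q limit, the ratio was 0.0595 for TET1 and 0.288 for TET2. At a fold enrichment of 10 or more it was 0.319 and 1.02, the latter from 96 against 94 peaks. Both of these settings were chosen after seeing the data. Of the DMSO peaks, 4.59% of TET1 (4.07 to 5.15), 24.7% of TET2 (22.3 to 27.2) and 31.9% of TET3 (31.1 to 32.6) were retained, each against a mean of 0.308% or less after circular and 0.540% or less after local shifts. Among equal numbers of the strongest peaks, 44.1% of TET1 and 51.7% of TET2 peaks were retained. Among BPK-25 peaks, 38.5% of TET1, 40.3% of TET2 and 65.8% of TET3 were new. Under DMSO, 83.2% of TET1 peaks, 84.8% of TET2 peaks and 82.6% of TET3 peaks overlapped an MBD3 peak, and 67.6%, 67.1% and 58.1% a CTCF peak.

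TET1 and TET3 shared many sites, and 59.3% of TET1 peaks under DMSO and 79.0% under BPK-25 overlapped a TET3 peak of the same treatment. With those peaks left out of both lists, 94 TET1 peaks stood against 2425, a ratio of 0.0388, and 0.289% of the remaining DMSO peaks were retained. With the DMSO list alone so reduced, which can only raise the ratio, it was 0.184. The DMSO TET1 list also had a local background of up to 374 times the genome background in a region of chromosome 2 that was high in both TET3 lists. Outside regions of high local background, the strongest TET1 region with no BPK-25 peak nearby was chromosome 17, 1372407 to 1372907, with a fold enrichment of 39.6. In the TET2 lists the region of chromosome 17 from 1372451 to 1372909 was retained, with 50.4 under DMSO and 19.8 under BPK-25. TET2 regions that were not retained included chromosome 1, 67520069 to 67520399, at 24.1, and chromosome 10, 74114518 to 74115037, at 20.0. For TET3 the strongest such region was chromosome 10, 5895537 to 5895905, at 16.4. All 5 top new regions of each TET protein lay in high local background.

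The BPK-25 TET3 list held more of the strong CTCF sites than the DMSO list, in a comparison that was not fixed beforehand. In the strongest decile of DMSO CTCF peaks, 16.3% (15.6 to 17.0) overlapped a DMSO TET3 peak and 37.6% (36.6 to 38.6) a BPK-25 TET3 peak, whereas in the weakest decile the shares were 8.98% and 3.42%. Of the 9627 DMSO TET3 peaks not retained, 55.1% overlapped a DMSO CTCF peak, and of the 8791 new BPK-25 peaks 54.4%, but the CTCF sites differed. Where summits lay within 200 bp, the median DMSO CTCF fold enrichment was 7.50 at the peaks not retained and 91.9 at the new TET3 peaks. The new peaks lay closer to the CTCF summit, with a median distance of 16 bp at overlapping sites against 153 bp. In the strongest decile, BPK-25 TET3 peaks overlapped 36.0% (34.9 to 37.2) of the CTCF sites that were retained in the BPK-25 CTCF list and 41.3% (39.6 to 43.2) of those that were not. For DMSO TET3 peaks the order was the other way, at 18.5% (17.6 to 19.4) and 11.05% (9.93 to 12.2). Among TET1 peaks, 32.0% of the 172 new (25.1 to 39.5) overlapped a DMSO CTCF peak, with a median CTCF fold enrichment of 96.3 and a median summit distance of 25 bp; the shares were 68.3% for the DMSO peaks not retained and 49.1% for BPK-25 peaks seen before. Of the new TET2 peaks, 18.0% (13.0 to 24.0) overlapped a DMSO CTCF peak, with a median CTCF fold enrichment of 15.6 and a distance of 69 bp, against 15.8 and 72.5 bp for the TET2 peaks not retained.

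**Figure D3:**
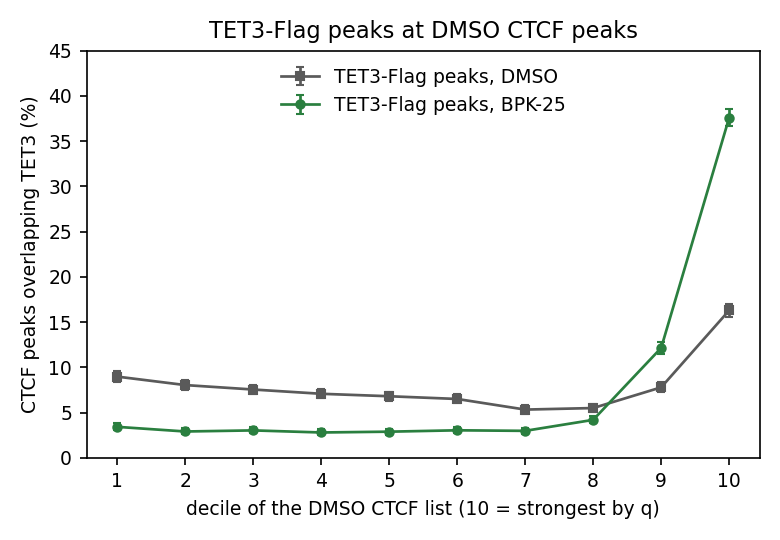
Share of DMSO CTCF peaks that overlap a TET3-Flag peak, in percent, by decile of the DMSO CTCF list ranked on -log10 q, for the DMSO (squares) and BPK-25 (circles) TET3 lists, with Clopper-Pearson 95% intervals as bars. The BPK-25 points lie below the DMSO points in the first 8 deciles and above them in the 9th, at 12.1% against 7.79%, and in the strongest, at 37.6% against 16.3%.

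Local background, which reflects the input, was at least 20 times the genome background in 72 regions over the 10 lists. The chromosome 1 region from 121484363 to 121485419 had 3319 to 3921 times in the TET lists, and 3540 and 5496 times in the CTCF lists. In 4 regions, singled out after the values were seen, at least 1 TET list reached 20 times while all 4 CTCF and MBD3 lists had peaks below it, and 3 of these exceeded 100 times. In the TET3 lists it reached 877 times the genome background under DMSO and 706 times under BPK-25 on chromosome 2, between 74213523 and 74329312. In the TET1 lists it reached 167 and 119 times on chromosome 10, between 70332139 and 70451564. On chromosome 6, 74229760 to 74230962, it was 425 and 162 times for TET1, 37.0 and 11.4 times for TET2, and 767 and 431 times for TET3. The other region was chromosome 19, 55625977 to 55628242, at up to 23.8 times in the TET lists. In the CTCF and MBD3 lists it was at most 2.64 times in these regions. In the chromosome 2 region the DMSO TET1 list reached 374 times and the TET2 lists 19.1 and 5.53 times, while the BPK-25 TET1 list had 0 peaks there, which leaves its local background unknown. The DMSO TET3 list had up to 46.3 times in the chromosome 10 region, against 2.41 in the BPK-25 TET3 list.

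**Figure D4:**
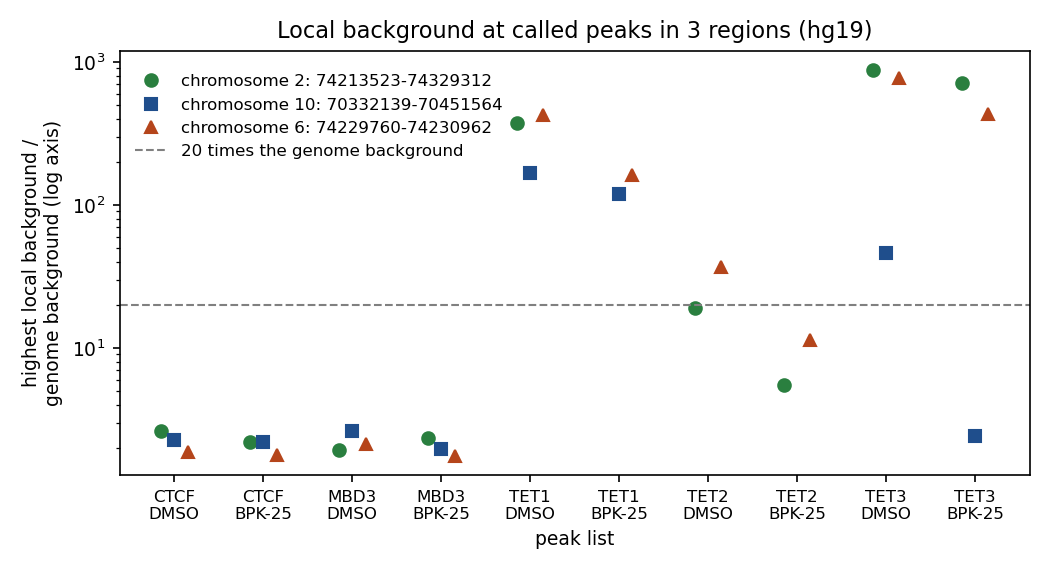
Highest local background at a called peak over the genome background of the list, on a log axis, in 3 hg19 regions for each of the 10 peak lists, with 20 times the genome background as a dashed line; lists without a peak in a region have no point there. The CTCF and MBD3 points are at most 2.64, and the DMSO TET1 point of the chromosome 2 region is at 374.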

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

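The tests in this part were all chosen after the result was seen. The DMSO TET1 list had a local background of up to 374 times the genome background on chromosome 2, between 74213523 and 74329312. Local background was at most 2.62 times there in the CTCF and MBD3 lists, 19.1 and 5.53 times in the TET2 lists, and 877 and 706 times in the TET3 lists. On GRCh38.p14 TET3 is on chromosome 2 and 151868 bp long, against 115790 bp between the outermost blocks, and TET1 is on chromosome 10 and 134151 bp long, against 119426 bp for the blocks there, so the tagged constructs are a candidate source for these lines; for TET2, on chromosome 4 and 133929 bp long, 8 of the 9 regions of high local background on that chromosome, at most 58191 bp long, were high in a CTCF or MBD3 list too, and the other, of 1271 bp, had 0 peaks in those lists. Material of the TET3 line in some DMSO TET1 samples could give the 374 times, but without a BPK-25 TET1 peak on chromosome 2 this stays open. Material of the TET1 line could give the 46.3 times of the DMSO TET3 list in the chromosome 10 region, where the BPK-25 TET3 list had at most 2.41 times. That difference is what such material in the DMSO samples alone would give, but other sources were not tested and it stays open too. Whether material of another line adds to the 59.3% of DMSO TET1 peaks at TET3 peaks or to the drop from 5951 to 447 TET1 peaks is also open. So is whether such material gives the 19.1 and 5.53 times of the TET2 lists on chromosome 2, which was not tested. Reads of the TET1 construct mapping to chromosome 2 are argued against, since the highest pileup there was 2.56 times (counting interval 2.36 to 2.79) that of the chromosome 10 blocks, and an input of the TET3 line used as the whole control is argued against by an interquartile range of 0.456 in the ratio of TET1 and TET3 local backgrounds under DMSO, against 0.0504 for MBD3 and CTCF. Which replicates would be concerned cannot be read from pooled lists, and no biological explanation was tested.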

How the results depend on the processing

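No paired analysis was possible because each list pools the replicates, although the labels share replicate numbers, and for the same reason no replicate could be left out in turn. Motif and promoter alternatives were not run, since no hg19 sequence or annotation was used. The ratio of BPK-25 to DMSO peak numbers kept its direction and stayed within 1.5 times its value in 21 of 37 alternatives, those for chromosomes, merging, equal pileup over background and high local background among them. At a -log10 q of 5 or more it was 1.33 for CTCF, 0.169 for TET1, 0.658 for TET2 and 1.28 for TET3, and at 10 or more 0.590 for CTCF, 1.94 for MBD3, 0.329 for TET1, 0.916 for TET2 and 1.49 for TET3, so that the direction turned for CTCF at 10 and for TET3 at both. At a fold enrichment of 10 or more, chosen after seeing the data, it was 0.0436 for CTCF, 0.436 for MBD3, 0.319 for TET1, 1.02 for TET2 and 1.80 for TET3, and the direction turned for each of these but TET1. Without the peaks that overlap TET3, also chosen afterwards, the TET1 ratio was 0.0388, and 0.184 where only the DMSO list was so reduced, a step that can only raise it. The cause of the turns was not tested. Equal pileup over background was a weak check, because most called peaks already met it. For CTCF it kept 99381 of 99587 DMSO peaks and all 245419 BPK-25 peaks, so the ratio had little room to change.

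The retained share stayed within its 95% interval in 14 of 42 alternatives. Otherwise it was 28.1% for CTCF, 58.5% for MBD3, 11.6% for TET1, 38.7% for TET2 and 33.1% for TET3 at a -log10 q of 5 or more, and 16.8% for CTCF, 51.5% for MBD3, 21.9% for TET1, 48.9% for TET2 and 35.1% for TET3 at 10 or more. It was 38.0% for CTCF, 61.9% for MBD3 and 32.8% for TET3 with intervals within 500 bp merged, 28.1% for CTCF, 50.1% for MBD3, 3.11% for TET1 and 23.01% for TET3 with 50% of the peak covered, and 27.4% for CTCF, 45.7% for MBD3 and 28.5% for TET3 with summits within 200 bp. With equal numbers of strongest peaks it was 27.8% for CTCF, 41.7% for MBD3, 44.1% for TET1, 51.7% for TET2 and 33.1% for TET3. After seeing the data, leaving out high local background gave 21.2% for TET2, and leaving out the peaks that overlap TET3 0.289% for TET1, or 0.701% where only the DMSO list was reduced. The share of CTCF peaks overlapping MBD3, under DMSO and BPK-25, was 28.5% and 71.3% at a -log10 q of 5 or more, 21.2% and 70.7% at 10 or more, 35.3% and 67.8% with intervals merged, 27.4% and 63.1% with 50% covered, 29.0% and 58.6% with summits within 200 bp, and 34.4% and 69.3% with equal numbers, higher under BPK-25 each time. Matched on peak width, retention of CTCF peaks with MBD3, TET1, TET2 and TET3 exceeded that of matched sets by 29.0, 21.99, 22.4 and 26.7 percentage points, against 30.2, 29.8, 29.3 and 33.9 matched on fold enrichment. Shifts of 100 kb to 1 Mb gave a larger share by position, 10.7% for CTCF, 14.0% for MBD3 and 0.540% for TET3 retention, and 3.94% and 14.4% for CTCF with MBD3 under DMSO and BPK-25, all below the observed shares. The cause of these differences was not tested. At the genome background a peak needed a pileup of at least 3.10 times that background in the BPK-25 CTCF list and 7.64 times in the BPK-25 TET2 list, so weaker enrichment was not detectable there.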

Other observations

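The common Flag sites, the correlations across chromosomes and the tests of explanations in this part were chosen after the data were seen. A set of sites was common to the Flag lists of all 3 TET lines. Under DMSO, 65.1% of TET2 peaks (62.4 to 67.8) overlapped both a TET1 and a TET3 peak, as did 13.3% of TET1 and 5.58% of TET3 peaks. Under BPK-25, 54.1% of TET1 peaks (49.4 to 58.8), 47.9% of TET2 peaks and 1.82% of TET3 peaks did. Under DMSO, the common sites of the TET3 list overlapped an MBD3 peak in 92.9% of cases and a CTCF peak in 73.2%, against 82.0% and 57.2% of its other peaks. They were also stronger, with a median fold enrichment of 6.95 against 4.29. Under BPK-25, the shares at a DMSO CTCF peak were 41.2% of the common and 57.1% of the other TET3 peaks, 39.7% and 45.9% for TET1, and 38.9% and 28.7% for TET2. High local background held 57 of the 243 common TET3 peaks, 55 of the 242 for TET1 and 53 of the 244 for TET2. Parental cells without a Flag construct were not analysed here, so sites that the Flag antibody enriches in any cell were not separated from TET sites. Material of another line in the pooled TET1, TET2 or TET3 samples, which stays open, would also add common sites. In the chromosome 2 region the TET2 lists too were raised, at 19.1 times the genome background under DMSO and 5.53 times under BPK-25. The CTCF and MBD3 lists had at most 2.62 times there. The shares of common sites therefore do not measure how far the TET proteins bind together.

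In most lists, peaks were dense on the chromosomes that are rich in genes. Across 23 chromosomes, which are not independent replicates, peaks per Mb of the DMSO CTCF list correlated with protein-coding genes per Mb (gene numbers from GRCh38.p14) with a Pearson r of 0.957 and a Spearman rho of 0.904. The permutation p was 1e-05 for both, the smallest that 100000 permutations can give, and 2.5e-05 and 2e-05 after Benjamini-Hochberg adjustment over the 10 lists. Without chromosomes 17 and 19, the farthest from the median gene density, r was 0.891. For BPK-25 CTCF r was 0.856 and rho 0.819. For the BPK-25 TET1 list r was 0.691 (permutation p = 0.00183, adjusted 0.00183) and rho 0.370 (permutation p = 0.0854, adjusted 0.0854), and without chromosomes 17 and 19 r was 0.0816. The BPK-25 TET2 list was alike, with r of 0.710 (permutation p = 0.00148, adjusted 0.00164), rho of 0.399 (permutation p = 0.0617, adjusted 0.0686) and r of 0.0923 without them, so in these 2 lists the relation rests on chromosomes 17 and 19.

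The BPK-25 CTCF list was longer than the DMSO list, yet it lacked or held only weakly many strong DMSO sites. Lower depth is argued against: of the 60519 DMSO peaks not retained, 92.4% had a pileup over background at least 2 times the lowest that the BPK-25 list called. An exchange of CTCF and MBD3 labels under BPK-25 is argued against as the only source. At shared sites of the strongest decile, the median pileup over background of the BPK-25 MBD3 list was only 3.52% of the DMSO CTCF median. Whether labels were exchanged on top of a lower CTCF signal cannot be told. The BPK-25 medians at sites of that decile shared with DMSO CTCF were 12.0 times the genome background for CTCF and 12.1 times for MBD3. Weak immunoprecipitation in the BPK-25 CTCF samples and lower CTCF occupancy of the cells cannot be told apart, because both may give a list close to that of MBD3 (Spearman rho 0.776 of pileups across 128599 shared sites, which are not independent replicates) and each treatment has 1 pooled CTCF list.

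The BPK-25 TET3 list gained peaks at the strongest CTCF sites. Carry-over of CTCF library material could place such peaks, and at shared sites of the strongest CTCF decile the pileups of DMSO CTCF and BPK-25 TET3 had a Spearman rho of 0.537 with summits a median of 12 bp apart, against 0.350 and 27 bp for DMSO TET3. Carry-over stays open. The share at BPK-25 TET3 peaks rose from 4.20% in the 8th decile to 12.1% and 37.6% in the next, the order carry-over would give. Yet no further rise was resolved among the strongest, as the 1000 peaks of highest CTCF pileup exceeded the next 4000 by 0.775 percentage points (-2.68 to 4.23). Ranked on -log10 q, as the deciles were, the share was 44.9% (43.6 to 46.3) of the 5000 strongest CTCF peaks. It was 42.2% (39.1 to 45.3) of the 1000 strongest and 40% (30.3 to 50.3) of the 100 strongest, so it did not rise towards the top on that ranking either. Greater depth is argued against by a genome background of 0.970 times that of the DMSO list. An effect of the treatment on where TET3 binds remains open as a hypothesis, since 1 pooled list per treatment does not separate it from differences between preparations.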
